A study of Mus musculus with 3 samples.

How the data were processed

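The values used were the deposited expression tables, which the authors gave as natural log (ln) values, ln of 1 plus 10000 times the UMIs of a gene over the UMIs of the cell. Per the submitters' processing notes, reads were aligned to mm10 and counted with Cell Ranger 1.3.1, and cells were filtered and normalised with Seurat 2.0.0. The strand used in counting, the gene annotation and the thresholds of the cell filter are not given in the sources used here. Per the labels' protocols, the libraries were 10x Genomics 3' libraries of RFP-positive cells sorted after somatic cells were removed.

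All 5023 cells summed to 10000 within rounding once the log was undone. The smallest non-zero value of a cell stands for 1 UMI, so its whole UMIs could be recovered, and 100.0% of 20140203 non-zero values were whole numbers within 0.01. The design had foreseen differences of mean ln values of at least 0.5 if the tables held normalised values. Because whole UMIs were recovered, sums of UMIs were used as the main values, and the ln means are given as an added alternative.

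The tables named their columns by library, and the names ending in 1 and 2 for the knockdown libraries were matched to shRNA1 and shRNA2 by that last digit. The match rests on the digit alone. If it were wrong, the values of hairpin 1 and hairpin 2 would change places, and statements on both hairpins would stand.

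No cell was removed. The tables held cells with at least 1637 genes and 7018 UMIs and at most 22.9% mitochondrial UMIs. The doublet caller of scanpy marked 8, 7 and 5 cells (0.56%, 0.4% and 0.27% of the libraries). Whether it found most doublets was not tested, and the cells it marked were kept. Whether doublets had been removed before deposit is not given in the sources used here.

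Cells were clustered with scanpy 1.11.5 on Python 3.11.15 from 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 0.8, with igraph 0.11.9 and leidenalg 0.10.2, which gave 18 clusters. No batch correction was used, since library and group are the same. Clusters were named from 12 marker lists fixed beforehand, each needing at least 3 raised markers (1.5-fold), and a class name means cells like that class. The 5 germ classes were spermatogonia, leptotene to zygotene spermatocytes, pachytene to diplotene spermatocytes, round spermatids, and elongating and condensing spermatids. A cluster with markers of both Sertoli cells and elongating spermatids was kept as mixed, and 3 clusters were set apart as non-germ. Cluster 10 was counted as round spermatids on a narrow margin (mean log2 marker score 0.53 against 0.39 for pachytene), and cluster 7 as spermatogonia (1.87 against 1.61 for leptotene to zygotene).

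UMIs were summed over the cells of a class and library and divided by the total of the class. A gene was compared if its mean was at least 10 CPM and its UMIs numbered at least 30, and folds used a pseudocount of 1 CPM. A class was compared if each library held at least 50 of its cells. Genes were counted if at least 2-fold from the control with both hairpins, judged on the fold alone. By a fixed rule, genes with the same direction in both were ranked by the smaller of their absolute folds, and the first 10 per direction were picked in all cells and in round spermatids and the first 3 elsewhere, with Gm4665, the main protamine and transition protein genes, Akap3, Ip6k1 and Acrv1, and up to 4 members per list. In the other classes some picked genes are not printed, and some other genes, such as Cd74 in spermatogonia, are given beside them. A fold from a control with no UMI is given as a lower bound.

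Since sharing 1 control ties the folds together, a null was drawn from 100 simulations of unchanged libraries. The noise of each library was drawn from the differences between the hairpins for genes of similar expression. The control thus had the noise of a hairpin library, also in classes where it held fewer UMIs. The 13 gene lists were fixed beforehand and covered chromatin of spermatids, acrosome, flagellum, glycolysis, piRNA, translational control, synapsis, meiotic divisions, apoptosis, immediate-early and heat shock genes, interferon, ubiquitin and X-linked germ cell genes. A list with at least 5 compared members was placed among 10000 random lists matched on mean expression in 10 bins. None of the markers for Leydig, myoid, mesenchymal, endothelial or red blood cells passed the expression filter over all cells.

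Gene positions came from GENCODE vM21 (mm10), in which 95.7% of the gene symbols were found. Near-identical transcripts were sought with blastn 2.17.0. For shares of cells with a UMI and for an alternative clustering, cells were thinned to 10000 UMIs. This left out 70, 530 and 332 shallower cells of the control, hairpin 1 and hairpin 2 libraries. Other tools were numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1, the last only for an alternative.

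The steps were tested on simulated data with known differences. All 50 genes set 3-fold higher in both knockdown libraries were counted, in all cells and in round spermatids. Of 50 genes set 3-fold lower, 40 and 41 were counted, the others having dropped below the expression filter. None of the genes set 1.5-fold apart was counted, and none of the 6815 and 6469 unchanged genes. This simulation held counting error only, far less than the spread between libraries used for the null, under which unchanged genes do pass.

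Alternatives covered scaling, expression filter, pseudocount, weighting of cells, cluster resolution, clustering without Gm4665, thinned cells, removal of doublet calls, and each hairpin alone. Cell order along a trajectory, splicing and transcript isoforms were not analysed here.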

Results

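Gm4665 is a mouse long non-coding RNA gene whose role in spermatogenesis was examined by knockdown in the living testis. Per the labels and the design text, AAV9 vectors carrying a short hairpin and a red fluorescent protein (RFP) were injected into the testes of ICR mice on postnatal day 21, with the control hairpin on one side and a hairpin against Gm4665 on the other. Somatic cells were then removed, RFP-positive germ cells were sorted, and their 3' RNA was sequenced from droplets. The series held 3 libraries: the control hairpin (shCtrl) and 2 hairpins against Gm4665, called hairpin 1 (shRNA1) and hairpin 2 (shRNA2) here. Each library was described as cells of 3 mice, and whether the control testes came from the same animals as the knockdown testes is not given in the sources used here.

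The control, hairpin 1 and hairpin 2 libraries held 1418, 1732 and 1873 cells with values for 22843 genes. The control cells were the deepest, with a median of 19366 UMIs per cell against 14667.5 and 16518, and median genes per cell of 3566, 3351.5 and 3752. Mitochondrial transcripts took a mean of 0.662%, 1.22% and 1.43% of the UMIs of a cell. Each group was 1 library, so the comparisons carry no test, and the hairpin cannot be separated from other differences between the libraries. Levels are UMIs summed over cells and scaled to 1000000 UMIs (CPM), and folds are log2 values against the control. The ranges given are 95% intervals (exact Poisson for sums, Clopper-Pearson for shares) and cover counting error only. For the genes named over all cells and in round spermatids, the counting interval of the ratio to the control excluded equality with either hairpin.

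Gm4665 RNA was lower with both hairpins in every class of cells. Over all cells it stood at 311 CPM (305.6 to 316.5) in the control, 52.8 (50.5 to 55.1) with hairpin 1 and 79.1 (76.5 to 81.8) with hairpin 2, which was 5.9 and 3.93 times lower. Round spermatids held 210.1 CPM (202.3 to 218.2) in the control, against 19.7 (17.3 to 22.4) and 37.8 (34.4 to 41.3), a level 10.6 and 5.56 times lower. Elongating and condensing spermatids held the highest control level among the germ classes, 479 CPM (468.5 to 489.7), against 114 (108.0 to 119.5) and 202 (193.7 to 210.9), which was 4.21 and 2.37 times lower. Leptotene to zygotene spermatocytes held 152, 14.9 and 38.4 CPM. Spermatogonia (64.0, 10.5 and 23.5 CPM) and pachytene to diplotene spermatocytes (49.4, 9.8 and 14.4 CPM) were lower, and apart from spermatogonia with hairpin 2 they were near the level of the non-germ cells (52.7, 10.2 and 10.8 CPM), which were expected to lack a germ cell RNA, so free RNA in the droplets is an open source of this signal.

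**Figure D1:**
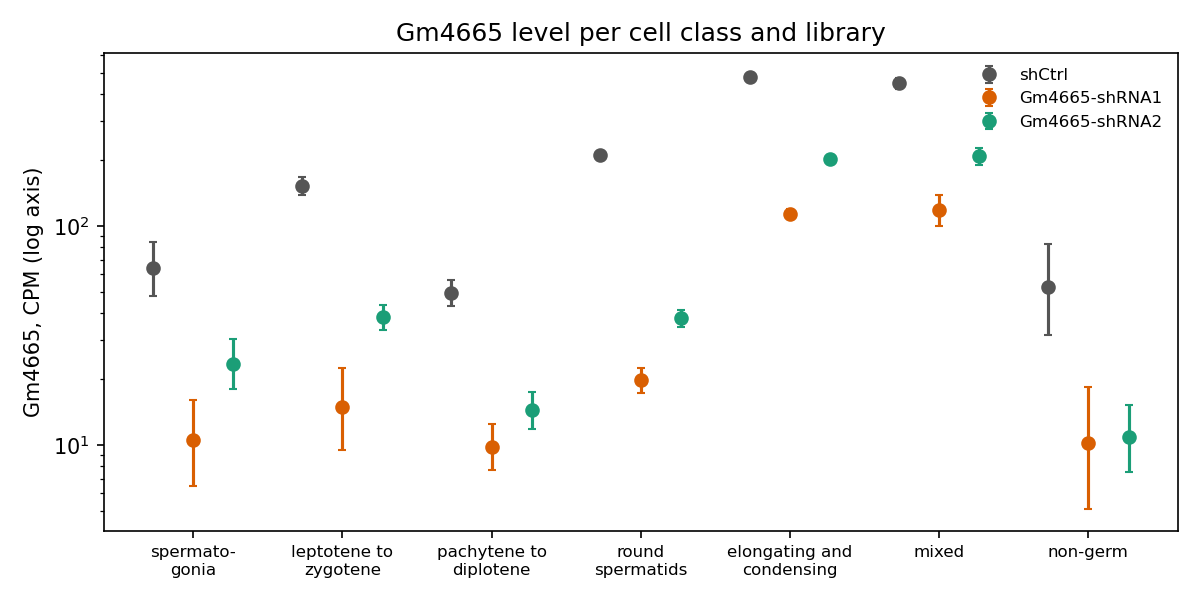
Gm4665 level (CPM, log axis) in 7 classes of cells from the control and both hairpin libraries, with points for UMI sums and bars for 95% Poisson intervals. The level was lower with both hairpins in all classes, from 479 to 114 and 202 CPM in elongating and condensing spermatids.

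At least 1 Gm4665 UMI was seen in 92.0%, 43.1% and 52.7% of all cells at median depths of 19366, 14667.5 and 16518 UMIs. Of the 1348, 1202 and 1541 cells deep enough to be thinned to 10000 UMIs, 79.0%, 35.1% and 39.8% held at least 1. Round spermatids gave 91.5%, 28.6% and 45.1% (thinned 75.3%, 18.5% and 27.0%), and elongating and condensing spermatids 97.0%, 71.9% and 88.9% (thinned 91.7%, 63.1% and 80.4%). Non-germ cells, which should lack the gene, gave 61.9%, 8.6% and 15.8% at median depths of 13957, 9676 and 13007 UMIs (thinned 33.3%, 9.8% and 11.1%).

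Gm4665 lies on chromosome 9 at 115180404 to 115186058 on the minus strand, as 2 exons inside an intron of Osbpl10, which runs on the plus strand and encodes an oxysterol-binding protein. The exons of the genes do not overlap. The strand used in counting is not given in the sources used here, so intronic Osbpl10 reads over these exons cannot be told apart from Gm4665 reads. Osbpl10 itself was at 116, 104 and 89.0 CPM in all cells (log2 -0.16 and -0.38), a far smaller difference than that of Gm4665.

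Elongating and condensing spermatids made up less of both knockdown libraries than of the control, and spermatogonia and pachytene to diplotene spermatocytes made up more. Among all cells, elongating and condensing spermatids were 42.8% (40.2 to 45.4), 37.0% (34.7 to 39.3) and 25.04% (23.1 to 27.1) of the control, hairpin 1 and hairpin 2 libraries. Round spermatids were 29.8%, 29.0% and 25.5%. Pachytene to diplotene spermatocytes were 5.99% (4.82 to 7.36), 11.8% (10.3 to 13.4) and 13.0% (11.5 to 14.6), and spermatogonia 3.81% (2.87 to 4.94), 8.66% (7.38 to 10.1) and 9.5% (8.21 to 10.9). Leptotene to zygotene spermatocytes split the hairpins, with 5.92% in the control, 4.1% with hairpin 1 and 11.4% with hairpin 2. Of the cells in the 5 germ classes alone, elongating and condensing spermatids took 48.4%, 40.8% and 29.7%, spermatogonia 4.31%, 9.57% and 11.3%, and pachytene to diplotene spermatocytes 6.78%, 13.0% and 15.4%. Among spermatids alone, elongating and condensing ones were 58.9% (55.9 to 62.0), 56.0% (53.1 to 58.9) and 49.6% (46.3 to 52.8), so with hairpin 1 the intervals overlapped.

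**Figure D2:**
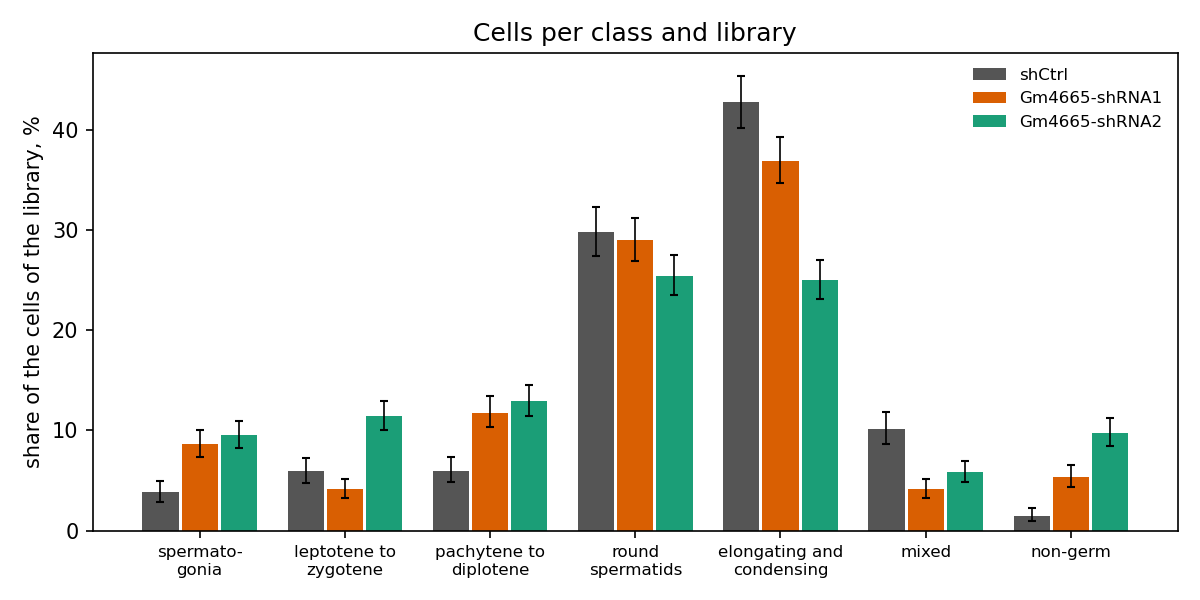
Share of the cells of each library (%) in 7 classes for the control and both hairpin libraries, with 95% Clopper-Pearson bars. Elongating and condensing spermatids were 42.8%, 37.0% and 25.04% of the libraries, and spermatogonia 3.81%, 8.66% and 9.5%.

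Elongating and condensing spermatids consisted of clusters 0, 1, 8 and 9, whose sizes differed unevenly between libraries. Cluster 1 held 82, 277 and 186 cells of the control, hairpin 1 and hairpin 2 libraries, and cluster 9 held 143, 84 and 48. Cluster 8 was led by Gm4665 itself, so the knockdown alone can move cells out of it. With Gm4665 left out of the clustering, elongating and condensing spermatids were 40.9%, 28.8% and 19.6% of the libraries, and round spermatids 33.1%, 37.3% and 30.7%. Round spermatids consisted of clusters 2, 3, 10 and 11, with 141, 143 and 245 cells in cluster 2 and 226, 150 and 109 in cluster 3. Thinning to 10000 UMIs before clustering left out 70, 530 and 332 cells of the control, hairpin 1 and hairpin 2 libraries. Among the cells kept it gave 47.0%, 43.2% and 29.7% for elongating and condensing spermatids, 25.4%, 13.4% and 16% for round spermatids, and 9.1%, 23.4% and 18.8% for pachytene to diplotene spermatocytes. A mixed cluster took 10.2%, 4.1% and 5.82% of the cells and non-germ cells 1.48%, 5.37% and 9.77%. The shares depend on the RFP sort, on the removal of somatic cells and on depth as well as on the testis, and these cannot be separated with 1 library per group.

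Over all cells, meiotic division genes were higher and marker genes of late spermatids lower in both knockdown libraries than in the control. Ranked by the smaller of the log2 folds, Jchain stood first, the joining chain of secreted IgM and IgA, with 5.77 CPM (5.05 to 6.56) in the control, 521 (513.5 to 528.0) with hairpin 1 and 925 (916.0 to 933.9) with hairpin 2. Genes of late spermatids such as Akap4, a fibrous sheath protein, were lower at 1155, 771 and 660.1 CPM. Of 7068 genes that passed the expression filter, 87 were at least 2-fold higher and 35 at least 2-fold lower with both hairpins. The median fold of all genes was 0.23 and 0.25, so a gene near these values stood level with the bulk of genes, and folds and list medians are best read against them.

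Among the most elevated genes were Mzb1, a chaperone of antibody-secreting cells (8.74, 74.2 and 158 CPM), the protease inhibitor Slpi (0.12, 77.3 and 11.5 CPM, the control value resting on 5 UMIs), and the surface antigens Ly6a (4.58, 26.6 and 46.8 CPM) and Cd52 (12.7, 51.7 and 157 CPM). B2m, the light chain of class I histocompatibility molecules, was at 43.0, 174 and 245 CPM. Atp6v1e2, a testis subunit of the vacuolar proton pump, was at 18.2 CPM (16.9 to 19.5), 109 (106.2 to 112.8) and 115 (111.6 to 117.9), and 1700023F02Rik at 10.3, 46.3 and 43.2 CPM. Rpap3, part of a chaperone complex that assembles RNA polymerases (3.89, 17.0 and 18.2 CPM), shares near-identical sequence with Gm5697, so its level is uncertain. Whether Tpm3-rs7 (0.72, 17.5 and 16.8 CPM) shares reads with Tpm3 was not tested, so its level is uncertain too.

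Gm4665 was among the genes with the lowest folds, but several others were further from the control. The transcript 1700104B16Rik was at 30.4 CPM (28.7 to 32.2) in the control against 0.99 (0.7 to 1.36) and 0.78 (0.55 to 1.09), and 4933433G15Rik at 35.7, 2.84 and 2.04 CPM. Tap1, which carries peptides to class I histocompatibility molecules, was at 24.0, 1.88 and 4.79 CPM, opposite in direction to B2m. Aacs, an enzyme that activates ketone bodies, was at 25.7, 5.19 and 5.76 CPM, and Esyt3, a membrane tether, at 29.4, 10.8 and 7.44 CPM. The antisense transcript Aknaos (25.6, 6.86 and 6.54 CPM) and the protein-coding genes AK157302 (52.6, 15.6 and 14.6 CPM) and 1700025G04Rik (58.1, 13.0 and 20.7 CPM) were lower as well. Dynlt1a, a dynein light chain at 39.1, 4.04 and 4.64 CPM, has a near-identical copy in Dynlt1f and its level is uncertain.

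Genes of the meiotic divisions stood above the bulk of genes. Of 26 members with enough UMIs, 25 were higher than in the control with both hairpins, with medians of 0.51 and 0.60. These medians lay at percentiles 99.97 and 99.93 of 10000 random lists matched on mean expression, as a description of these libraries. The kinetochore gene Cenpf was at 45.1, 92.9 and 92.9 CPM, and cyclin B1 (Ccnb1) at 73.4, 135 and 119.9 CPM. Marker genes of pachytene cells were also higher, with 9 of 10 above the control in both and medians of 0.46 and 0.49 (percentiles 99.0 and 97.7). The apoptosis list left the random range with hairpin 2 only (8 genes, 0.45 and 0.69, percentiles 92.6 and 98.2), and the immediate-early and heat shock list stayed inside it with both (12 genes, 0.42 and 0.45, percentiles 94.3 and 89.1). Single members that were higher were Bax, a pore-forming death effector (10.5, 21.3 and 31.9 CPM), and Junb, an early response transcription factor (6.93, 15.1 and 25.5 CPM). The synapsis list split the hairpins (18 genes, 0.07 and 0.48, percentiles 16.9 and 94.1), although Psmc3ip, a cofactor of strand exchange, was at 187, 399 and 316 CPM. Markers of leptotene to zygotene cells split them as well (9 genes, -0.17 and 0.68, percentiles 5.25 and 98.8).

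Genes of late spermatids stood below the bulk over all cells, where elongating and condensing spermatids were also fewer in both knockdown libraries. Within that class Prm1 was not lower (82994, 85957 and 95946 CPM), while Akap3 was (log2 -0.24 and -0.89). All 14 marker genes of elongating spermatids were lower with both hairpins, with medians of -0.48 and -0.67 and no random list lower. Prm1, the first protamine that packs sperm DNA, was at 51064, 40685 and 37783 CPM (log2 -0.33 and -0.43), Prm2 at 36751, 25485 and 23605, Tnp1 at 17254, 14137 and 12845, and Tnp2 at 15748, 12052 and 9715. The histone-to-protamine list as a whole (20 genes) had medians of -0.08 and -0.24 at percentiles 8.69 and 4.21, with Cdyl, a chromatin repressor, at 311, 214 and 156 CPM. Akap3, a fibrous sheath anchor, was at 374, 298 and 212 CPM (log2 -0.33 and -0.82), Gapdhs, the sperm form of a glycolytic enzyme, at 2818, 1911 and 1739.8 CPM, and Ip6k1, an inositol phosphate kinase, at 209, 161 and 137 CPM (log2 -0.38 and -0.61). Acrv1, an acrosomal protein, was near the control (0.12 and -0.10), and its fold with hairpin 1 was -0.15 under TMM scaling.

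Most other lists stayed inside the random range over all cells. X-linked germ cell genes were low with hairpin 1 (16 genes, -0.23 and -0.08, percentiles 0.81 and 8.18), with Cypt2 at -0.67 and -0.71 but Ssxb1 at 1.11 and 0.71. The acrosome list (30 genes, 0.10 and 0.02, percentiles 36.3 and 30.6), the flagellum list (52 genes, 0.21 and 0.10, percentiles 77.2 and 37.1) and the glycolysis list (21 genes, 0.08 and -0.05, percentiles 41.8 and 29.6) lay in the middle. So did the piRNA list (21 genes, 0.10 and 0.29, percentiles 27.1 and 76.0), the translational control list (23 genes, 0.29 and 0.33, percentiles 83.8 and 84.6) and the ubiquitin list (26 genes, 0.05 and 0.02, percentiles 20.5 and 25.2). Only 2 interferon genes had enough UMIs, so no median was computed. Markers of round spermatids (16 genes, 0.05 and -0.05) and of spermatogonia (5 genes, 0.49 and 0.45, percentiles 88.9 and 72.4) lay inside the random range, and of the somatic markers 4 Sertoli and 3 macrophage genes had enough UMIs, 2 of the latter being 2-fold higher.

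The split of higher and lower genes over all cells rests on the scaling. With TMM factors it was 31 higher and 185 lower, with median-of-ratios factors 30 and 206, and without the 20 most abundant genes 72 and 55, against 87 and 35. The 4 main protamine and transition protein genes alone took 12.1%, 9.2% and 8.4% of all UMIs. With the classes weighted to the mix of the control, 16 genes were higher and 15 lower.

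Folds with hairpin 1 and hairpin 2 followed each other across genes, with a Pearson correlation of 0.76 in all cells and 0.71 in round spermatids. Both folds share 1 control library, and unchanged libraries simulated with equal noise in each give a correlation of 0.5 by construction, whatever the spread. A control noisier than the hairpin libraries would give a higher value. Under that null, the mean count of genes at least 2-fold from the control in both was 24.0 higher and 23.5 lower in all cells, with at most 69 in all, against 87 and 35. In round spermatids it was 24.2 and 23.4, with at most 67, against 24 and 31, so with scaling by total UMIs the count there did not exceed the null. TMM and median-of-ratios factors gave larger counts in round spermatids, and no null was drawn for them. The spread between the hairpins also holds their unlike cluster mixes, such as 143 and 245 cells in cluster 2. The covariance of the folds was 0.248 against 0.0864 in all cells and 0.180 against 0.0827 in round spermatids. If the hairpins were independent, 10.1 higher and 2.3 lower genes would overlap in all cells and 1.9 and 2.4 in round spermatids. Part of any excess may come from the shared control, and 1 control library cannot be split to measure it.

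**Figure D3:**
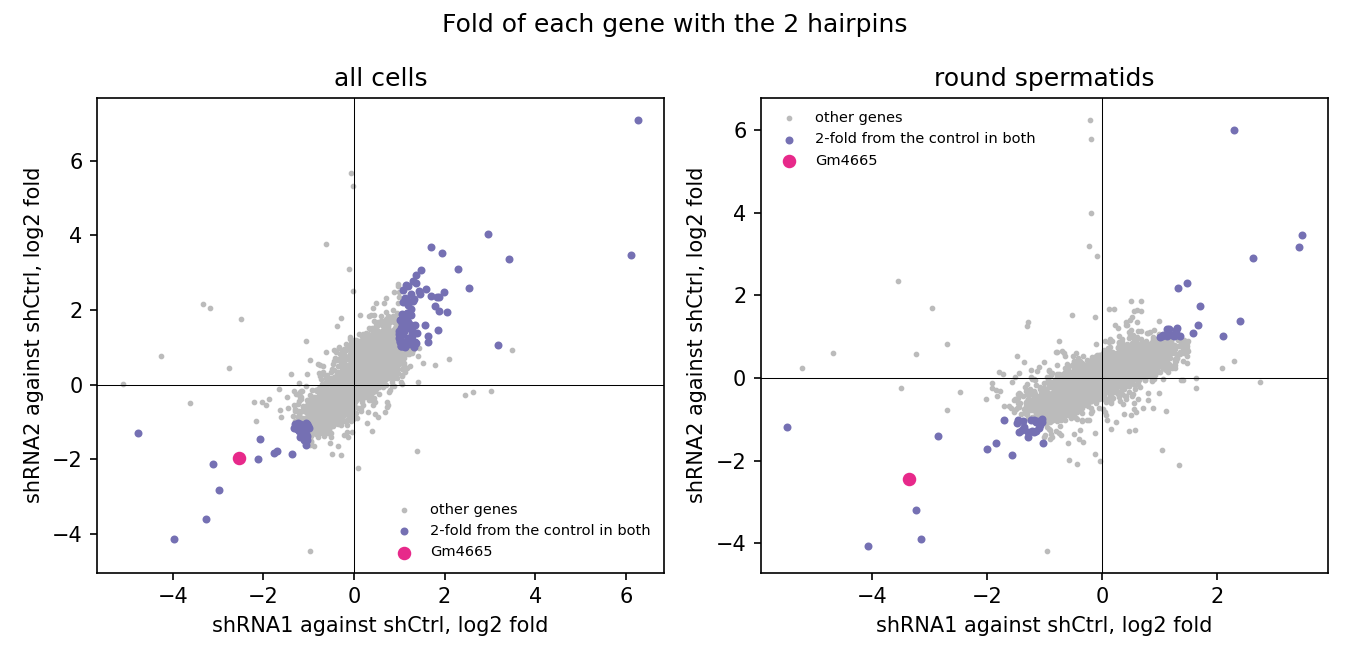
Log2 fold against the control with shRNA1 (x axis) and shRNA2 (y axis) for each gene in all cells and in round spermatids, with genes at least 2-fold from the control in both shown in colour and Gm4665 marked; there are no error bars. Folds followed each other with correlations of 0.76 and 0.71, and Gm4665 lay at -2.54 and -1.96 in all cells.

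Round spermatids, where the knockdown was deepest, held more RNA of the meiotic divisions and of spermatocyte markers with both hairpins, and less protamine and transition protein RNA. With the round spermatid clusters weighted to the mix of the control, the meiotic division and protamine differences were smaller with hairpin 1 and close to 0 with hairpin 2, although differences remained within some clusters. Prm1 was at 24113 CPM (24028 to 24198) in the control, 15521 (15450.1 to 15592) with hairpin 1 and 17602 (17529 to 17676) with hairpin 2. The spindle kinase gene Aurka was at 30.9, 68.7 and 53.7 CPM. Of 6702 genes, 24 were at least 2-fold higher and 31 lower with both hairpins, and the median fold of all genes was 0.16 and 0.10. With TMM factors the split was 12 higher and 73 lower, with median-of-ratios factors 12 and 70, and without the 20 most abundant genes 19 and 41.

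The other protamine and transition protein genes followed Prm1. Prm2 was at 16626, 9307 and 11444 CPM (log2 -0.84 and -0.54), Tnp1 at 10059.5, 6226 and 7426 (log2 -0.69 and -0.44) and Tnp2 at 9183, 5196 and 5829.7 (log2 -0.82 and -0.66). The histone-to-protamine list (19 genes) had medians of -0.31 and -0.11 at percentiles 0.26 and 2.81, with the spermatid kinase gene Tssk6 at 504, 292 and 339 CPM and Cdyl at 403, 239.9 and 273 CPM. Of the marker genes of elongating spermatids, 13 of 14 were lower in both, with medians of -0.66 and -0.48 and no random list lower. Akap3 was at 529 CPM (516.6 to 541.8), 419.7 and 395 (log2 -0.33 and -0.42), Akap4 at 922, 610.2 and 647, and Ip6k1 at 332, 235 and 247 (log2 -0.50 and -0.42). Acrv1 was close to the control at 499.6, 527 and 473 CPM, and its fold with hairpin 1 was 0.08, or -0.07 with TMM factors.

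Genes of the meiotic divisions were higher in round spermatids by medians of 0.68 and 0.38 (23 genes, percentiles 100 and 99.98), and 22 of the 23 were above the control in both. Besides Aurka they included Nusap1, a spindle protein (11.5, 27.8 and 20.2 CPM), and the cell cycle kinase gene Cdk1 (7.28, 12.6 and 11.6 CPM). All 10 pachytene markers were higher in both, with medians of 0.58 and 0.37 (percentiles 99.9 and 99.9). Markers of leptotene to zygotene cells had medians of 0.47 and 0.36 (8 genes, percentiles 94.3 and 97.0), and the synapsis list of 0.40 and 0.18 (15 genes, percentiles 97.45 and 81.75), with the chromosome axis gene Sycp3 at 22.8, 44.9 and 39.8 CPM. Markers of round spermatids stayed at 0.00 and -0.02 (16 genes). Weighted to the control's mix of round spermatid clusters, the meiotic division list had medians of 0.28 and -0.06 (percentiles 99.9 and 41.2). Under the same weighting the folds were -0.28 and 0.08 for Prm1, -0.49 and -0.02 for Prm2, -0.32 and 0.11 for Tnp1 and -0.39 and 0.01 for Tnp2. Within clusters, hairpin 2 still gave -0.42, -0.51, -0.42 and -0.74 for these genes in cluster 10 and -0.19, -0.33, -0.16 and -0.42 in cluster 2. In cluster 3 they were near the control (-0.03, -0.11, 0.0 and -0.11), with a meiotic division median of 0.23. In cluster 11 they were higher (0.39, 0.08, 0.48 and 0.26). Mitochondrial UMIs (0.161%, 0.361% and 0.255%) and depth (median 15714, 11486 and 14136 UMIs) of round spermatids also differed between the libraries. Whether RNA of spermatocytes reached the droplets of round spermatids was not tested.

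The most elevated single genes in round spermatids included Jchain (1.7, 12.3 and 172 CPM), which belongs to antibody-secreting cells. Atp6v1e2 was at 31.5 CPM (28.5 to 34.7), 199.9 (192.0 to 208.1) and 239.5 (231.1 to 248.2), 1700023F02Rik at 18.8, 64.0 and 65.4, and the glycosyltransferase gene Galntl6 at 5.35, 16.6 and 30.3. Psph, an enzyme of serine synthesis, was at 24.7, 63.0 and 115 CPM, Hilpda, a lipid droplet protein, at 5.66, 20.1 and 15.2, the mitochondrial complex I gene mt-Nd3 at 3.72, 23.7 and 11.3, and Gm12763 at 6.04, 16.3 and 15.3. Tpm3-rs7 (0.62, 17.0 and 16.7 CPM) and Rpap3 (0.85, 18.9 and 15.6 CPM) were higher with the same uncertainty over copies as above.

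Only 1700104B16Rik (41.2 CPM, 37.8 to 44.9, against 1.51 and 1.5), 4933433G15Rik (43.0, 3.95 and 1.97) and Dynlt1a (53.4, 4.79 and 4.9) were further below the control than Gm4665 by the smaller of their folds. Aacs (29.5, 6.64 and 8.22) and Aknaos (20.7, 5.04 and 6.24) came after it. Gm14151 (20.2, 6.13 and 4.82), 1700025G04Rik (42.1, 4.96 and 15.3) and 4921513I03Rik (22.7, 7.73 and 8.53) were lower too. Dynlt1a and the histone gene Hist2h2aa1 (31.4, 12.3 and 11.1) have near-identical copies, so which copy differed is uncertain.

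Other lists in round spermatids stood mostly inside the random range. X-linked germ cell genes had medians of -0.36 and -0.11 (16 genes, percentiles 0.23 and 3.68), and the ubiquitin list 0.05 and -0.11 (25 genes, percentiles 26.5 and 1.42), with the ligase gene Rnf133 at -0.90 and -0.57. Translational control genes had medians of 0.28 and 0.08 (21 genes, percentiles 92.1 and 46.8), and Pabpc6, a poly(A)-binding protein, was at 14.8, 37.6 and 34.1 CPM. In the heat shock list (10 genes, 0.16 and 0.20, percentiles 51.1 and 78.4) the endoplasmic reticulum chaperone Hspa5 was at 28.2, 70.8 and 58.5 CPM, and in the apoptosis list (6 genes, 0.31 and 0.26, percentiles 76.5 and 87.1) Diablo was at 64.5, 119.1 and 117. The acrosome list had 0.07 and 0.04 (30 genes, percentiles 40.6 and 35.3), although Zpbp2, a zona-binding protein, was at 289, 488 and 435 CPM. The flagellum list had 0.15 and 0.09 (52 genes, percentiles 73.2 and 66.9), the glycolysis list 0.09 and 0.04 (21 genes, percentiles 49.7 and 42.1) with the glucose transporter Slc2a3 at 20.4, 56.8 and 36.2 CPM, and the piRNA list 0.23 and 0.18 (18 genes, percentiles 82.9 and 87.5).

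**Figure D4:**
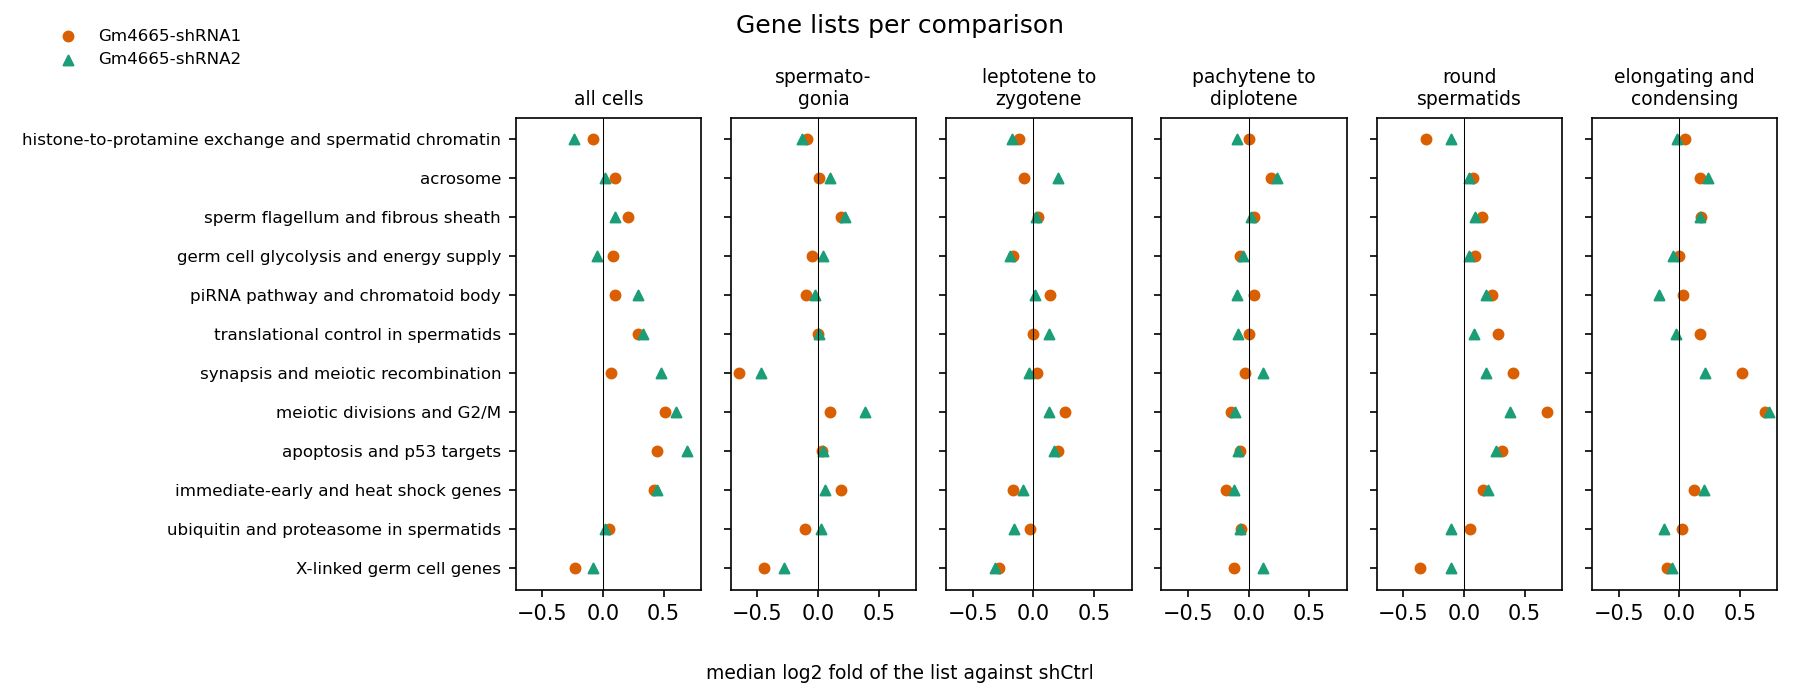
Median log2 fold against the control (x axis) of 12 gene lists in all cells and in the 5 germ classes, with circles for shRNA1 and triangles for shRNA2; there are no error bars. The meiotic division list was higher with both hairpins in round spermatids (0.68 and 0.38) and in elongating and condensing spermatids (0.71 and 0.74), and lower in pachytene to diplotene spermatocytes (-0.15 and -0.11).

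Elongating and condensing spermatids also held more RNA of the meiotic divisions with both hairpins, with medians of 0.71 and 0.74 (17 genes, percentiles 100 and 100; 15 above the control in both), but their protamine levels were close to the control. Cenpf was at 6.75, 16.1 and 15.4 CPM, Aurka at 14.4, 32.1 and 29.8, and Ccnb1 at 17.3, 36.3 and 34.4. Prm1 was at 82994, 85957 and 95946 CPM (log2 0.05 and 0.21), and with TMM factors its fold with hairpin 1 was -0.05. Akap3 was lower at 405, 342 and 218 CPM (log2 -0.24 and -0.89), and Ip6k1 at 189.8, 154 and 117 (log2 -0.30 and -0.69). The clusters of this class held different shares in each library, and weighted to the control's mix of clusters the meiotic division medians were 0.42 and 0.48 (percentiles 100 and 99.9), while Akap3 (0.05 and -0.15) and Ip6k1 (-0.08 and -0.16) were nearer the control. With hairpin 2 both stayed lower in cluster 1 (-0.79 and -0.38) and in cluster 9 (-0.32 and -0.37), and were nearer the control in cluster 0 (-0.15 and -0.07). In cluster 8 they were higher with each hairpin (Akap3 0.30 and 0.31, Ip6k1 0.17 and 0.32). Within clusters 0, 1, 8 and 9 the meiotic division medians were 0.86 and 0.82, 0.13 and 0.09, 0.40 and 0.61, and 0.59 and 0.65. Acrosome genes (30 genes, 0.17 and 0.24, percentiles 97.7 and 99.8) and flagellum genes (46 genes, 0.18 and 0.17, percentiles 99.91 and 99.95) stood slightly above the random lists, with Zpbp2 at 61.4, 123 and 133 CPM and Rsph1, a radial spoke protein, at 188, 327 and 368. Both lists lay inside the random range when only genes of at least 50 CPM were compared (smaller medians 0.15 and 0.02), and the acrosome list also with the control's mix of clusters (-0.03 and 0.17). All 8 pachytene markers were above the control in both (0.73 and 0.72, percentiles 99.99 and 99.98). Pachytene to diplotene cells were also more frequent in the knockdown libraries (5.99%, 11.8% and 13.0%). Whether RNA of spermatocytes reached the droplets of elongating and condensing spermatids was not tested.

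Of 5066 genes in elongating and condensing spermatids, 81 were at least 2-fold higher and 15 lower with both hairpins, and with TMM factors 51 and 22. Simulations of unchanged libraries gave 16.8 and 16.9. The top gene beside Jchain (1.03, 11.7 and 61.1 CPM) and Tpm3-rs7 (0.91, 18.4 and 13.9) was Atp6v1e2 at 14.5, 87.1 and 87.6 CPM. Aacs was lower at 30.7, 1.73 and 1.7 CPM, AK157302 at 77.3, 22.7 and 23.8, and Esyt3 at 34.4, 12.6 and 5.49. The synapsis list left the random range with hairpin 1 only (9 genes, 0.52 and 0.21, percentiles 99.7 and 90.1).

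Spermatogonia from the knockdown libraries held less RNA of genes that switch on at the entry into meiosis. The synapsis list had medians of -0.65 and -0.47 with no random list lower, and 27 of its 29 genes were below the control in both. Msh5, a crossover gene, was at 37.7 CPM (25.4 to 53.8), 15 (10.1 to 21.3) and 14.9 (10.6 to 20.5), Prdm9, which places recombination hotspots, at 46.4, 21.4 and 14.1, and Tex12, a part of the synaptonemal complex, at 77.8, 29.9 and 33.8. All 11 markers of leptotene to zygotene cells were lower (-1.02 and -0.71), including Tex101 at 756, 308 and 387 CPM, while the 12 markers of spermatogonia stayed at -0.14 and -0.04. Markers of other classes differed as well, with 13 of 14 elongating spermatid markers lower (-0.41 and -0.43, percentiles 0.01 and 0) and pachytene markers higher (0.31 and 0.46, percentiles 99.2 and 99.9), so RNA of other cells differed between the libraries in this class. X-linked germ cell genes were lower (26 genes, -0.45 and -0.28, percentiles 0.01 and 0.06), and flagellum genes higher (44 genes, 0.19 and 0.22, percentiles 99.9 and 99.9), with the dynein gene Dnah8 at 13.8, 35.4 and 73.4 CPM. The flagellum result was lost when only genes of at least 50 CPM were compared (smaller median 0.01) and without the doublet calls (0.11). The control held only 54 spermatogonia against 150 and 178, so another mix of early and late spermatogonia is an open alternative. Cluster 7, which held most of these cells, scored 1.87 for spermatogonia and 1.61 for leptotene to zygotene spermatocytes, so the class reaches into early meiosis.

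Of 9000 genes in spermatogonia, 131 were at least 2-fold higher and 71 lower with both hairpins, where simulations gave 15.5 and 15.9. The control held 796590 UMIs here against 2006572 and 2548041 with the hairpins, but the simulations gave it the noise of a hairpin library. They thus understate its counting error, and the size of the excess over them is uncertain. H2-Aa, a class II histocompatibility chain, had no UMI in the control and 41.9 and 13.3 CPM with the hairpins, at least 11.1-fold and 3.5-fold higher, and A330032B11Rik no UMI and 42.9 and 24.3 CPM, at least 11.4-fold and 6.5-fold higher. Cd74 (2.5, 108 and 36.9 CPM) and Jchain (3.8, 10.0 and 770.4 CPM) were higher with H2-Aa, and non-germ cells were also more frequent in these libraries (1.48%, 5.37% and 9.77%), so RNA of immune cells is an open alternative for these genes. Primpol, a primase that restarts DNA synthesis, was lower at 26.4, 8.47 and 7.46 CPM, Rmdn1 at 20.1, 6.48 and 6.67, and BC028528 at 23.9, 6.48 and 0.39. The meiotic division list was higher mainly with hairpin 2 (33 genes, 0.10 and 0.39, percentiles 95.4 and 100), and the interferon list had -0.26 and -0.39 (6 genes, percentiles 15.9 and 5.46).

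Leptotene to zygotene spermatocytes held less protamine and sperm glycolysis RNA, which belongs to later cells. Prm1 was at 26115, 17121 and 16827 CPM, and all 14 elongating spermatid markers were below the control (-0.86 and -0.69, no random list lower). All 5 Sertoli markers with enough UMIs were lower too (-0.56 and -0.41, percentiles 0.97 and 1.6). The glycolysis list had -0.17 and -0.19 (21 genes, percentiles 0.45 and 0.38), with Gapdhs at 1305, 709 and 782 CPM, and X-linked germ cell genes had -0.28 and -0.32 (12 genes, percentiles 1.43 and 0.38). The synapsis list was near the control (27 genes, 0.03 and -0.04, percentiles 26.9 and 7.1). Of 7587 genes, 15 were at least 2-fold higher and 55 lower (simulations 12.5 and 12.7; 12 and 78 with TMM factors), among them 1700023F02Rik at 5.06, 27.9 and 25.7 CPM, Atp6v1e2 at 7.23, 34.4 and 46.4, and 4933433G15Rik at 43.0, 3.24 and 2.5. The control level of Prm1 here was above that in its non-germ cells (8984 CPM) and spermatogonia (11495 CPM), and how RNA of later cells came to be in this class was not resolved.

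By the count of 2-fold genes, pachytene to diplotene spermatocytes differed little from the control, and a few single genes had very large folds. Protamine RNA, which belongs to later cells, was lower here too. Prm1 was at 8058.5, 6794 and 7007 CPM and Prm2 at 5955, 4140 and 4845 in the control, hairpin 1 and hairpin 2 libraries. Dapp1, an adaptor of lipid signalling, was at 36.7 CPM (31.2 to 42.9) in the control and rested on 1 UMI in each knockdown library (0.14 and 0.13 CPM). 1700104B16Rik was at 82.8, 1.52 and 0.93 CPM and Dynlt1a at 133 (122.6 to 144.7), 6.36 and 5.87, while Atp6v1e2 was at 7.95, 60.9 and 70.1 and Gm43101 at 1.17, 17.8 and 26.7. In all, 11 genes were at least 2-fold higher and 12 lower of 6815, fewer than the 16.1 and 15.9 of the simulations. Acrosome genes were slightly higher (32 genes, 0.18 and 0.23, percentiles 99.96 and 100), with Lyzl6 at 95.9, 131 and 144 CPM, as were 14 of 15 round spermatid markers (0.26 and 0.26). The meiotic division list was lower (29 genes, -0.15 and -0.11, percentiles 0.1 and 1.53), with the kinase gene Aurkc at 29.2, 16.6 and 12.4 CPM and Cdk1 at 116, 75.6 and 85.3. This result was lost when only genes of at least 50 CPM were compared (smaller median -0.07) and with a pseudocount of 10 CPM (-0.07). The class consisted of clusters 4, 14 and 17. Cluster 17 held 14, 10 and 26 cells of the control, hairpin 1 and hairpin 2 libraries, at median depths of 100942, 75407.5 and 44921.5 UMIs. No weighting to the control's mix of clusters was made for this class, so another mix is an open alternative for its list and gene differences.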

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

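The patterns below were seen first, and of the tests put to them, the split of control cells by Dynlt1a, the carry-over of 4-fold genes, the sums over germ classes, the class mix, the cluster mix, the shared reads as the cause of the whole set and the subtraction of free Prm1 RNA were chosen only after the result was seen, while the predictions of the others were written before their values were computed.

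The non-germ cells of the knockdown libraries were rich in Jchain, the joining chain of secreted antibodies, at 18128 CPM (17875 to 18384) with hairpin 1 and 11700.4 (11579 to 11823) with hairpin 2, against 491 (421.5 to 569.2) in the control. Cluster 12, which held 3, 42 and 99 cells of the control, hairpin 1 and hairpin 2 libraries, carried most of it, with 1820.1, 34175 and 18144 CPM, and with Mzb1 at 2334, 4702 and 3133 CPM. Jchain also appeared in classes that do not make it. With hairpin 2 it stood at 770.4 CPM in spermatogonia, 172 in round spermatids and 61.1 in elongating and condensing spermatids, and with hairpin 1 at 10.0, 12.3 and 11.7. Germ cells are not known to make antibody chains, so the level of Jchain in these classes was not read as germ cell expression.

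In pachytene to diplotene spermatocytes 23 genes were at least 2-fold from the control with both hairpins, and 1700104B16Rik, Dapp1 and Dynlt1a by far more. Sequence variants that differ between ICR animals could produce this. In the control 36 of 85 such cells lacked Dynlt1a where depth alone gave 3.2. Between them and the 21 cells with at least 3 Dynlt1a UMIs, 35.7% of the other genes (5 of 14, 12.8 to 64.9) were at least 2-fold apart, against 1.92% of genes in general. Direction was not part of this test. Most knockdown pachytene cells lacked Dynlt1a (81.9% and 87.7%). At the low level of these libraries depth alone gave nearly as many, 163.9 and 204.1 cells where 167 and 213 were seen. Gm43643 was lower both in control cells without Dynlt1a (log2 -2.65) and with the hairpins (-1.91 and -1.79). Marc2 (3.01 against -2.43 and -2.78), 4933433G15Rik (3.13 against -3.81 and -3.89) and 1700023F02Rik (-3.51 against 2.46 and 2.28) went opposite ways. In control round spermatids split in the same way, such differences kept their direction in 56.1% of genes (64 of 114, 46.5 to 65.4). The prediction had set so low a share against donor variants, but this test cannot decide. Of the 129 genes apart, 40.1 were expected from counting error alone, which lowers the share that can carry over. Round spermatids were also shallower than pachytene cells (control medians 15714 and 48465 UMIs). Cells there can thus lack a Dynlt1a UMI by depth alone, and those with at least 3 are more likely deep ones. For genes at least 4-fold apart, a restriction chosen afterwards, the share was 100% (13 of 13, 75.3 to 100). Reads shared between near-identical transcripts do not explain the set as a whole, since 71.4% of the genes (15 of 21; 47.8 to 88.7) had no such copy, but they stay open for the 28.6% that did (6 of 21; 11.3 to 52.2, against 19.3% of random genes). If loss of Gm4665 drove the set, the deeper knockdown should give the larger fold, and hairpin 1 gave it for 36.4% (8 of 22; 17.2 to 59.3), which neither shows nor excludes a part of Gm4665. With donor variants neither shown nor excluded and no test that decides on Gm4665, the largest folds are best not taken as targets of Gm4665.

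The genes higher in both knockdown libraries over all cells could come from the kinds of cells sampled. When only the germ classes were summed, 55.2% (48 of 87) were still at least 2-fold higher, and those that were not included Mzb1, Cd79a and Lyz2 as well as Ncl, Cenpf and Rpl39, while Jchain, Slpi and Cd74 stayed. With the classes weighted to the mix of the control, 17.2% (15 of 87) stayed 2-fold higher. The second value met the prediction for a mix of classes, but it counts genes that still pass a 2-fold line. Genes near that line drop out with small changes, and TMM scaling, which leaves the mix as it was, also lowered the number of higher genes. How much of the higher genes comes from the mix of classes was therefore not settled. The mix itself may come from the sort or from the testis, which these libraries cannot separate.

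In round spermatids the higher meiotic division genes and lower protamine genes could come from younger spermatids in the knockdown libraries. Leaving out cluster 10, the one nearest to spermatocytes, left medians of 0.51 and 0.32 where they had been 0.68 and 0.38, which speaks against that cluster as the only source. Weighted to the control's mix of clusters, the medians were 0.28 and -0.06, and within clusters 2, 3, 10 and 11 they were 0.16 and 0.05, 0.37 and 0.23, -0.01 and -0.11, and -0.08 and -0.12. For the 4 protamine and transition protein genes the weighted folds were -0.28 to -0.49 with hairpin 1 and -0.02 to 0.11 with hairpin 2, and of 8 folds per cluster 6 were at or below -0.2 in cluster 2, 1 in cluster 3, 8 in cluster 10 and 0 in cluster 11, so the mix stays open for both hairpins. Free protamine RNA stays open as well. Subtraction of the pachytene, spermatogonia or non-germ level left Prm1 at 0.54 and 0.66, 0.50 and 0.73, and 0.20 and 0.66 of the control. The leptotene to zygotene level (26115 CPM in the control) was above the round spermatid level (24113 CPM). These CPM levels came from classes of unlike depth, with control medians of 48465 UMIs in pachytene cells and 15714 in round spermatids. The subtraction therefore did not measure free RNA per droplet and cannot decide.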

How the results depend on the processing

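Of the tests in this part, the ln means, limma, the class mix of the control, the sums over germ classes, clustering without Gm4665, spermatids by cluster or cluster mix, and the alternatives for the other germ classes were chosen only after the result was seen. The other alternatives were set before the data were examined. No paired analysis was possible because the labels do not tie a knockdown library to a control library of the same animals, and there was 1 control library.

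Scaling moved the count of genes at least 2-fold from the control with both hairpins. Over all cells, 122 genes became 216 with TMM factors (66 shared) and 236 with median-of-ratios factors (65 shared). In round spermatids, 55 became 85 with TMM factors (43 shared). Leaving out the 20 most abundant genes gave 127 and 60. Gm4665 with TMM factors was at 358, 50.2 and 72.1 CPM over all cells. Within round spermatids alone, without TMM factors, it was at 210.1, 19.7 and 37.8. The cause was not tested.

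The expression filter and the pseudocount changed counts by construction, since they change which genes are compared or how small counts are weighed. With a mean of at least 50 CPM, 28 genes were left over all cells and 10 in round spermatids, and with no filter 311 and 139. A pseudocount of 10 CPM gave 37 over all cells and 13 in round spermatids, and 41 of 202 in spermatogonia, 16 of 70 in leptotene to zygotene spermatocytes, 14 of 23 in pachytene to diplotene spermatocytes and 14 of 96 in elongating and condensing spermatids, all shared with the first count.

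With only hairpin 1 considered, 237 genes over all cells and 409 in round spermatids were at least 2-fold from the control, and with only hairpin 2 693 and 140. Differences of ln means of at least 0.5 left 22 genes over all cells (4 shared), 6 in round spermatids (3 shared), 6 in spermatogonia, 2 in leptotene to zygotene spermatocytes, 2 in pachytene to diplotene spermatocytes and 5 in elongating and condensing spermatids. When limma took the hairpins as replicates, 14 genes over all cells (11 higher) and 10 in round spermatids (5 higher) passed an adjusted p of 0.05, and 2337 and 1554 had an unadjusted p below 0.05. The lowest adjusted p was 4.94e-05 and 0.00566, and it borrows its spread from the hairpins, since 1 control has none. The count models edgeR and DESeq2 were not run, since the deposited unit is ln and the recovered UMIs were used for sums, folds and intervals only.

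With the class mix of the control, 31 genes over all cells were left (26 shared), and summing germ classes only left 91 (75 shared). Within round spermatids, cluster 2 alone gave 22 genes (16 shared) and cluster 3 alone 32 (19 shared), where fewer cells were summed, and leaving out cluster 10 gave 43. Removing the doublet calls gave 119 and 56, but the caller marked only 20 of 5023 cells, so this alternative could change little. A filter of at least 500 genes removed no cell.

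Shares depended on the clustering, and the cause was not tested. For elongating and condensing spermatids in the hairpin 1 and hairpin 2 libraries, clustering without Gm4665 gave 28.8% and 19.6% and resolution 0.5 gave 39.6% in the control, 28.7% and 19.5%, while thinned cells gave 47.0%, 43.2% and 29.7%. For round spermatids the values were 33.1%, 37.3% and 30.7% without Gm4665, 33.0%, 37.4% and 31.0% at resolution 0.5 and 25.4%, 13.4% and 16% with thinned cells. Thinned cells gave 9.1%, 23.4% and 18.8% for pachytene to diplotene spermatocytes. At resolution 1.2, leptotene to zygotene spermatocytes were 5.5% with hairpin 1, and spermatogonia 2.5% in the control and 7.3% with hairpin 1. The other 67 shares lay within their counting intervals.

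Of the list placements, 309 stayed, 7 were stronger and 9 weaker. A filter of 50 CPM, which leaves fewer genes, placed further lists outside the random range, with the median nearer to 0 at -0.29 and -0.47 for the chromatin and X-linked lists over all cells, -0.16 and -0.21 for them in round spermatids, and -0.17 for chromatin and 0.14 for meiotic divisions in spermatogonia. It brought flagellum genes in spermatogonia (0.01), meiotic divisions in pachytene cells (-0.07), and acrosome (0.15) and flagellum (0.02) genes in elongating spermatids inside the range. Flagellum genes in spermatogonia were also inside it without doublet calls (0.11), meiotic divisions in pachytene cells with a pseudocount of 10 CPM (-0.07), and meiotic divisions in cluster 2 alone (0.05). With the control's mix of clusters, meiotic divisions in round spermatids (0.28 and -0.06) and acrosome genes in elongating spermatids (-0.03 and 0.17) no longer left the range with both hairpins, having medians of opposite sign with a common size of 0, although hairpin 1 alone kept meiotic divisions outside it, and piRNA genes in elongating spermatids were outside it (0.19). Of the folds of named genes, 490 stayed within their counting interval and 382 moved, and none at least 2-fold from the control reversed.

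Depth limits what can be seen. Genes below a mean of 10 CPM were not compared, and levels in classes with few control cells, such as the 54 spermatogonia, have wide counting intervals.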

Other observations

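No further tests were chosen for this part after the result was seen, and the values below are descriptions without a test.

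The mixed cluster carried Sertoli cell genes together with the RNA of condensing spermatids. It held 144, 71 and 109 cells of the control, hairpin 1 and hairpin 2 libraries and raised 8 of 10 Sertoli markers and 12 of 14 elongating spermatid markers. Defb19, a defensin made by Sertoli cells, was at 565.5 CPM (538.2 to 593.8), 274 (245.5 to 303.7) and 323 (300.4 to 346.9), Cst12, a cystatin, at 252, 106 and 124, and the chaperone gene Clu at 127, 70.5 and 45.8. Prm1 in this cluster was at 93901, 97927 and 107740.3 CPM. Whether the cluster holds doublets, free RNA or cells attached to each other was not tested.

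The non-germ cells fell into 3 clusters. Cluster 12, led by Jchain, took 0.21% (0.04 to 0.62), 2.42% (1.75 to 3.26) and 5.29% (4.32 to 6.4) of the libraries. Cluster 16, with 5, 33 and 18 cells, was macrophage-like and raised 8 of 8 macrophage markers. Its lysozyme gene Lyz2 was at 2012, 4923 and 1635 CPM and its complement gene C1qa at 107, 2062 and 614, while Cd74, the invariant chain of class II molecules, was highest in the control at 31315, 21431 and 17818. Cluster 13 was left without a name, since it raised 6 of 6 mesenchymal markers while immune genes were also among those that led it. Its leading genes included Cd74 at 10716, 9474 and 9322 CPM, the transcription factor gene Ebf1 at 409, 503 and 428, Mgp at 270.5, 146.0 and 480.6 and Igfbp7 at 302.4, 241.6 and 389.2. Cluster 13 took 0.92% (0.49 to 1.56) of the control, 1.04% (0.62 to 1.64) with hairpin 1 and 3.52% (2.74 to 4.46) with hairpin 2. Slpi in cluster 12 separated the hairpins, at 30.8 CPM in the control, 5034 with hairpin 1 and 195 with hairpin 2.

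Protamine RNA was found in every class. Prm1 was at 8984, 12519 and 7689 CPM in the non-germ cells of the control, hairpin 1 and hairpin 2 libraries and at 11495, 9273 and 8406 in spermatogonia. Both classes should lack it, and its source was not tested. In leptotene to zygotene spermatocytes the control was higher at 26115 CPM, against 17121 and 16827.

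Genes around Gm4665 gave no common direction. Within 1000000 bases, 4 of 21 genes had enough UMIs. Osbpl10, the host of Gm4665, was at 116, 104 and 89.0 CPM (log2 -0.16 and -0.38), and Stt3b, a glycosylation enzyme, at 193, 184 and 157 (log2 -0.08 and -0.30). Cnot10, part of the deadenylase complex, was at 11.2, 17.6 and 17.9 CPM (log2 0.61 and 0.63). Rps27rt was at 146, 225 and 274 (log2 0.62 and 0.90), a gene that shares sequence with other copies of a ribosomal protein gene. The bulk of genes stood at 0.23 and 0.25 in these libraries.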
